A study of Mus musculus with 6 samples.

How the data were processed

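Total RNA of the cervical spinal cord was sequenced in 6 C57BL/6 mice, 3 controls and 3 with allergic contact dermatitis (ACD) induced by squaric acid dibutylester (SADBE), a contact allergen. Per the labels' protocols, 20 µl of 1% SADBE in acetone was put on the shaved abdomen on 3 days. After an interval of 5 days the ACD group received 20 µl of 1% SADBE on the shaved nape on 3 days, and the controls received acetone alone. The labels do not make clear whether the controls were sensitised on the abdomen as well. They call the 3 samples of each group biological replicates, and the design text names 6 mice, so each library was taken as 1 mouse. The groups and replicate numbers came from the sample descriptions. The labels give no day of dissection or library preparation, so a difference in handling between the groups was not tested, and any difference between ACD and control can include one.

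The deposited values are FPKM (fragments per kilobase of exon, scaled to a common library size), 1 table per library with 54532 Ensembl gene identifiers, as the values themselves show: their low values are whole multiples of what 1 read is worth at a gene's exon length. The submitters' processing notes name HISAT2 2.0.5, featureCounts 1.5.0-p3, DESeq2 1.16.1 and the genome build mm10, without saying which step each was used for. The library kit, whether counting used strand, and the annotation release are not given in the sources used here. Without known strand, reads of a gene and of an overlapping antisense gene cannot be told apart. Symbols were matched for 54409 identifiers, and 54495 were found in GENCODE M21 (GRCm38, the same build as mm10), which gave gene types, exon lengths and the coordinates printed here.

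The tests planned before the data were examined were count tests, with a stated fallback for normalized values. Because the files hold FPKM and not counts, the fallback was the test used: limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with trend and robust settings) on log2(FPKM + 0.1), for the genes with a mean of at least 0.1 FPKM over the 6 libraries. This left 21369 genes. P-values were adjusted by the Benjamini-Hochberg method over these genes and the threshold was 0.05. All adjusted p-values of genes are from this fit, and fold changes are ACD minus control on the log2(FPKM + 0.1) scale, which understates the change of low genes. Levels are mean FPKM ± SD with n = 3.

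Before the data were examined, 41 gene lists were fixed: markers of the cell types a cervical cord dissection can hold, immune and signalling pathways, itch and pain transmission, stress responses, and sets for checking the libraries. Each list with at least 3 tested members was tested with camera at a preset inter-gene correlation of 0.01, two-sided, adjusted over the 41 lists. Camera with an estimated correlation and fry, read by its directional p and by its p for changes in either direction, were run beside it. For each list the members past 0.05 were counted over all genes and again adjusted over the list alone. The genes named were chosen by a rule fixed beforehand: the 10 largest rises and 10 largest falls among genes that passed, with a mean of at least 1 and no overlap between the groups, skipping predicted genes and pseudogenes; up to 4 passing members of each list, or the member with the smallest p where none passed; and Gfap, Aif1, Lcn2, Stat3, Il33, Grp, Grpr, Npr1 and Tacr1 whatever their result. The rule was written for CPM and was applied to FPKM. Not every gene that the rule covers is reported here. Any other named gene was chosen after its values were seen, among them the other examples given for lists.

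Multiplying an FPKM by the exon length and by a denominator per library gave whole reads, within 0.05, for 96.9% of the values above 0. All 6 values were whole for 97.1% of the genes with a value above 0. The denominators, taken as the depth, were 16916600, 18583992 and 17342466 reads for controls 1 to 3 and 17346315, 20245576 and 18293033 for ACD 1 to 3. The recovered reads summed to 0.976, 1.018 and 1.027 times the denominators of controls 1 to 3. For ACD 1 to 3 they summed to 1.068, 1.061 and 1.040 times, so a denominator is not the read total. At these depths 1 read in a 2 kb transcript is worth 0.0247 to 0.0296 FPKM, and a value of 0, with a limit of 3 reads, allows up to 0.0741 to 0.0887 FPKM, for counting error alone. The recovered reads were used to give the depth behind a call and for an alternative fit with voom.

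The fit was tested on simulated data made from the real libraries' means and depths, with 200 changed genes among 21329 tested. Every simulated gene had the same dispersion of 0.0052, a median over genes, and the changed genes were drawn from those with at least 20 mean reads. Genes that vary more are therefore not covered, recovery was not measured for lower genes, and the figures may be too favourable. It recovered 49.3% of genes changed 1.5-fold, 85.1% of those changed 2-fold and 92.4% of those changed 4-fold. Of its 175 calls 24 were false, and 20 of these had under 10 mean reads. With no gene changed, 18 of 21342 simulated genes were called, all with under 10 mean reads. Calls with under 10 mean reads are therefore counted separately.

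To find genes that share sequence, 75-base words of each gene's longest transcript were compared with those of all other genes. Where a named gene's share of such words is printed and is not 0%, its value is uncertain, because the counting of reads that fit several genes is not given in the sources used here. The share is not printed beside every gene: Ctla2a has 7.4%, H2-T23 7% and H2-D1 6.9%. Pairs of libraries within a group differed by more than sampling noise, with a chi-square per gene of 5.01 to 18.41, so none was treated as a duplicate. The alternatives were other pseudocounts, scalings, filters, a voom fit, a replicate block, another threshold, leaving out dominant transcripts and leaving out each library in turn. Further settings were added after the data were seen: a read minimum, removal of the trend on exon length and GC content, median-of-ratios and TPM scaling, and protein-coding nuclear genes only. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used for joining and plotting.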

Results

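RNA from the cervical spinal cord was sequenced in 3 control mice challenged with acetone and 3 mice with SADBE-induced allergic contact dermatitis (ACD), an itching skin inflammation of the nape, an area supplied by cervical segments. The values were FPKM, with a depth of 16916600 to 18583992 reads in controls and 17346315 to 20245576 in ACD libraries, recovered from the steps between low values. Between 24982 and 25870 genes had a value above 0 in the control libraries and between 23511 and 24194 in the ACD libraries. Correlations between libraries were 0.947 to 0.955 within controls, 0.972 to 0.974 within ACD and 0.944 to 0.956 between the groups, across genes, which are not independent replicates. The first principal component, with 35.6% of the variance, separated the 3 control from the 3 ACD libraries.

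The single comparison asked which transcripts of the cervical cord differ when the skin of the nape is inflamed. In the ACD cords 6 of 29 interferon-stimulated genes, 7 of 19 antigen presentation genes, 9 of 19 genes of the unfolded protein and heat shock response and 3 of 14 genes of activated vessels rose, and none of these lists had a gene that fell. Isg15, a ubiquitin-like protein induced by interferon, went from 2.81 ± 0.763 FPKM in controls to 7.52 ± 1.73 in ACD. Hspa5, the chaperone BiP, went from 54.5 ± 3.40 to 93.9 ± 7.46. The nuclear long non-coding RNAs Malat1 and Meg3 were lower, Malat1 at 151 ± 25.4 in controls and 30.6 ± 9.53 in ACD, and Meg3 at 101 ± 6.40 and 31.1 ± 5.40. The astrocyte filament gene Gfap rose from 413 ± 33.4 to 576 ± 38.5, while the itch receptors Grpr and Npr1 did not pass the test.

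Of 21369 genes tested with limma, 927 passed an adjusted p of 0.05, 386 higher and 541 lower in ACD. With voom on recovered reads 2474 passed (1203 higher, 1271 lower), without a filter 556, with the replicate block 181 and with 1 library left out 192 to 736. In each of the 927 the 3 ACD values and the 3 control values did not overlap. Passing with 3 values in each group nearly requires this, so it adds no support. Non-overlapping groups were seen in 6115 of all genes tested, or 28.6%, where chance gives 10%. At least 2-fold differences were seen in 104 of the higher and 265 of the lower genes. A mean of under 10 recovered reads lay behind 136 calls, 120 of them lower, which leaves 370 higher and 421 lower genes with at least 10 reads among 16748 tested. The balance of higher and lower calls moved with the scaling: 41.6% of calls were higher in the FPKM as deposited, 22.8% (208 higher, 704 lower) after TPM scaling and 63.8% (888 higher, 504 lower) after a trend on exon length and GC content was removed. TPM scaling moved the median log2 fold change of all genes from -0.01 to -0.10.

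Among the genes with the largest rises, Sprr1a, a cornified envelope precursor that injured neurons also express, went from 0.142 ± 0.0746 to 1.97 ± 0.728 FPKM (log2 fold change 3.08, SE 0.33, adjusted p = 0.00923). It lies on chromosome 3 at 92483952 to 92485895 and rested on 15.5 mean reads. Ptgs2, the inducible prostaglandin synthase, on chromosome 1 at 150100031 to 150108227, went from 0.328 ± 0.0982 to 1.79 ± 0.536 (2.12, SE 0.28, adjusted p = 0.0150). Apold1, an endothelial gene, went from 1.57 ± 0.703 to 4.80 ± 1.62 (1.58, SE 0.33, adjusted p = 0.0497). Ifitm2, which restricts virus entry and shares 42.0% of its words with other genes, went from 5.72 ± 1.15 to 15.1 ± 2.39 (1.39, SE 0.17, adjusted p = 0.0121). The mitochondrial transfer RNA mt-Tl1 went from 71.3 ± 12.2 to 240 ± 57.4 (1.74, SE 0.19, adjusted p = 0.00923).

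Of 29 tested interferon-stimulated genes 6 rose and none fell, and 16 rose when adjusted over the list alone. The median log2 fold change was 0.75 (camera adjusted p = 1.12e-11; adjusted p = 0.491 with an estimated correlation). By the directional p of fry this list alone among the 41 passed, with an adjusted p of 0.0441. By its p for changes in either direction 25 lists passed. Isg15 rose by 1.40 on the log2 scale (SE 0.24, adjusted p = 0.0274). Ifitm3, another restriction factor, rose from 20.5 ± 3.99 to 44.2 ± 3.03 FPKM (1.12, SE 0.14, adjusted p = 0.0121). Usp18, the protease that removes Isg15 from proteins, rose from 0.536 ± 0.0151 to 1.32 ± 0.173 (1.15, SE 0.16, adjusted p = 0.0180). Ifit3b, with 35.7% of its words shared, rose from 2.93 ± 0.227 to 4.53 ± 0.249 (0.62, SE 0.09, adjusted p = 0.0207). The summed haemoglobin genes, a marker of blood, were higher in each ACD library than in each control as well, at 596 ± 149 against 252 ± 144 FPKM.

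In the antigen presentation list 7 of 19 genes rose and none fell, 10 when adjusted over the list alone, with a median of 0.57 (camera adjusted p = 9.27e-06; adjusted p = 0.491 with an estimated correlation). The classical class I heavy chains H2-K1 and H2-D1, on chromosome 17, went from 18.1 ± 2.24 to 30.0 ± 1.46 FPKM (0.73, SE 0.10, adjusted p = 0.0146) and from 34.7 ± 2.87 to 52.2 ± 1.78 (0.59, SE 0.08, adjusted p = 0.0133). H2-T23 rose by 0.67 (adjusted p = 0.0218), H2-Q6 by 1.44 (adjusted p = 0.0263, 17.4% of words shared) and H2-DMa, which loads class II molecules, by 0.59 (adjusted p = 0.0234). The class II genes H2-Aa (0.04), H2-Eb1 (0.04) and H2-Ab1 (-0.36), with Cd74 (-0.02) and Ciita (-0.54), did not pass (adjusted p of 0.351 to 0.985), nor did they with any 1 library left out. Cd74, H2-Aa and H2-Eb1 were at 0.45, 0.39 and 0.35 without control 1 and at -0.42, -0.35 and -0.27 without control 3, so they show no direction. Of 13 complement genes 3 rose over all genes and over the list alone, with a median of 0.25 (camera adjusted p = 0.0387; adjusted p = 0.507 with an estimated correlation). They were the C1q chains C1qa, at 44.5 ± 7.90 and 70.7 ± 4.05 FPKM (0.68, SE 0.13, adjusted p = 0.0348), C1qb (0.63, adjusted p = 0.0331) and C1qc (0.58, adjusted p = 0.0239), which microglia make in the cord.

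Among homeostatic microglia markers 2 of 15 rose and none fell, 4 when adjusted over the list alone (median 0.27, camera adjusted p = 0.00244; adjusted p = 0.507 with an estimated correlation). Tmem119 rose from 7.87 ± 0.996 to 11.4 ± 0.603 FPKM (0.53, SE 0.10, adjusted p = 0.0394) and Olfml3 by 0.57 (adjusted p = 0.0384). The microglia marker Aif1 was at 2.67 ± 0.795 and 3.38 ± 0.172 (0.37, SE 0.19, adjusted p = 0.303) and did not pass. None of 16 microglia activation genes passed over all genes and 2 did so adjusted over the list alone (median 0.35, camera adjusted p = 0.0136; adjusted p = 0.491 with an estimated correlation); the smallest p was that of the protease Ctss (0.62, adjusted p = 0.0587). Of 13 reactive astrocyte genes 2 rose, 4 when adjusted over the list alone (median 0.36, camera adjusted p = 6.09e-04; adjusted p = 0.491 with an estimated correlation). Gfap rose by 0.48 on the log2 scale (SE 0.09, adjusted p = 0.0332), and the heat shock protein Hspb1, with 47.3% of its words shared, by 0.62 (adjusted p = 0.0274). Lcn2, the iron-binding lipocalin that neutrophils also make, was at 1.23 ± 1.00 and 5.30 ± 1.66 (2.25, SE 0.53, adjusted p = 0.0655). None of 12 homeostatic astrocyte genes passed (median 0.11, camera adjusted p = 0.139).

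**Figure D1:**
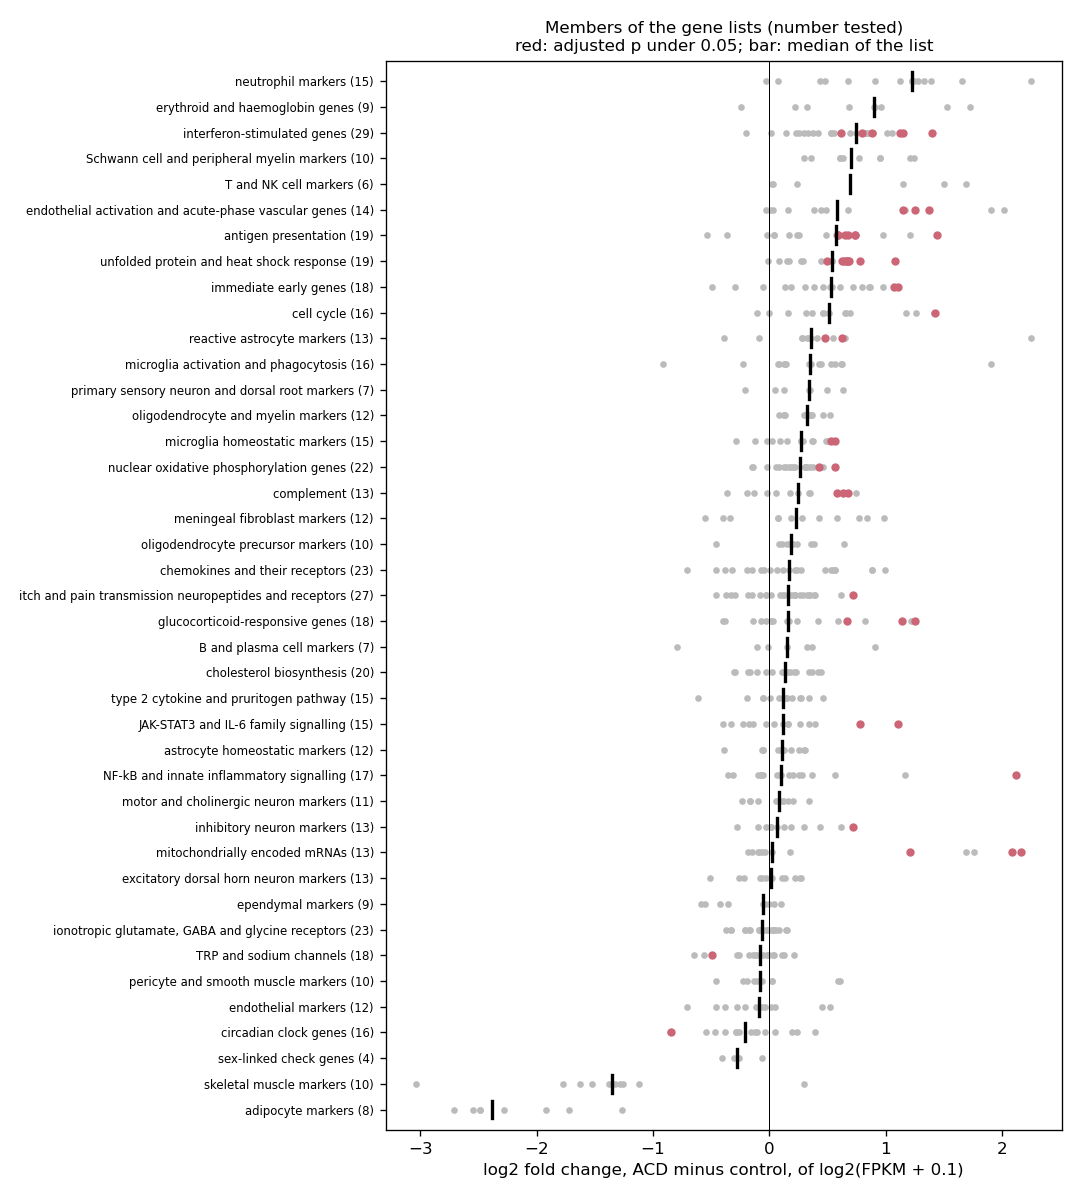
Log2 fold change (ACD minus control, horizontal axis) of each tested member of the 41 gene lists, with members past an adjusted p of 0.05 in red, the others in grey and a black bar at each list's median. The list medians run from -2.38 for adipocyte markers to 1.23 for neutrophil markers, with no passing member in either; that of the mitochondrially encoded mRNAs, 0.02 here, is -0.08 after TPM scaling.

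In the unfolded protein and heat shock list 9 of 19 genes rose and none fell, 13 when adjusted over the list alone (median 0.54, camera adjusted p = 1.95e-08; adjusted p = 0.491 with an estimated correlation). Besides Hspa5 (0.78, SE 0.08, adjusted p = 0.00903), the endoplasmic reticulum chaperone Hsp90b1 rose from 57.8 ± 0.649 to 91.5 ± 5.60 FPKM (0.66, SE 0.07, adjusted p = 0.00854). Sdf2l1 rose by 1.08 (adjusted p = 0.0155) and the disulfide isomerase Pdia4 by 0.65 (adjusted p = 0.0217). Of 14 endothelial activation genes 3 rose, 9 when adjusted over the list alone (median 0.58, camera adjusted p = 2.43e-05; adjusted p = 0.491 with an estimated correlation). Vwf, the von Willebrand clotting factor, rose from 2.03 ± 0.558 to 4.94 ± 0.852 (1.26, SE 0.21, adjusted p = 0.0253), Ctla2a from 1.39 ± 0.204 to 3.72 ± 0.199 (1.37, SE 0.13, adjusted p = 0.00697) and the angiopoietin Angpt2 by 1.15 (adjusted p = 0.0462). None of 12 general endothelial markers passed over all genes, with 1 higher and 1 lower adjusted over the list alone (median -0.09, camera adjusted p = 0.705).

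Of 18 glucocorticoid-responsive genes 3 rose, 4 when adjusted over the list alone (median 0.16, camera adjusted p = 0.0288; adjusted p = 0.528 with an estimated correlation). They were the cell cycle inhibitor Cdkn1a, at 11.1 ± 0.929 and 26.8 ± 3.91 FPKM (1.25, SE 0.12, adjusted p = 0.00713), and the metallothioneins Mt1 (0.67, adjusted p = 0.0203) and Mt2 (1.14, adjusted p = 0.0480), which other stresses also induce. Of 18 immediate early genes 2 rose, 7 when adjusted over the list alone (median 0.53, camera adjusted p = 1.14e-04; adjusted p = 0.491 with an estimated correlation): the transcription factor Junb (1.11, SE 0.20, adjusted p = 0.0334) and Ier2 (1.07, SE 0.21, adjusted p = 0.0394). Among 16 cell cycle genes 1, the cyclin Ccnb2, rose, 2 when adjusted over the list alone (median 0.51, camera adjusted p = 2.45e-05; adjusted p = 0.491 with an estimated correlation); it was at 0.224 ± 0.0445 and 0.765 ± 0.104 (1.42, SE 0.23, adjusted p = 0.0235). Per3 was the 1 of 16 circadian clock genes that fell, from 3.87 ± 0.652 to 2.10 ± 0.233 (-0.84, SE 0.14, adjusted p = 0.0278). Adjusted over the list alone 5 clock genes fell (median -0.21, camera adjusted p = 0.0493; adjusted p = 0.507 with an estimated correlation). None of 20 cholesterol biosynthesis genes passed (median 0.13, camera adjusted p = 0.0871).

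Among 27 neuropeptides and receptors of itch and pain transmission 1 rose, over all genes and over the list alone, and the list did not pass (median 0.16, camera adjusted p = 0.0855). It was Pdyn, the precursor of dynorphin, an opioid peptide of spinal inhibitory neurons that dampens itch, on chromosome 2 at 129686565 to 129699844. It rose from 4.01 ± 0.378 to 6.66 ± 0.557 FPKM (0.72, SE 0.10, adjusted p = 0.0169). The itch peptide Grp was at 6.20 ± 1.90 and 8.05 ± 2.19 (0.38, SE 0.29, adjusted p = 0.493), and its receptor Grpr at 0.621 ± 0.234 and 0.581 ± 0.187 (-0.08, SE 0.32, adjusted p = 0.912). The natriuretic peptide receptor Npr1 was at 1.29 ± 0.549 and 0.998 ± 0.192 (-0.29, SE 0.28, adjusted p = 0.587), and the substance P receptor Tacr1 at 2.12 ± 0.408 and 2.30 ± 0.113 (0.13, SE 0.15, adjusted p = 0.654). With an SE of 0.32 on 27.5 mean reads, a moderate change of Grpr was not detectable here.

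The JAK-STAT3 list had 2 of 15 genes higher, over all genes and over the list alone, Il6ra (0.78, adjusted p = 0.0274) and Junb, and did not pass (median 0.12, camera adjusted p = 0.125). Stat3 itself was at 8.70 ± 0.824 and 9.73 ± 0.436 FPKM (0.16, SE 0.09, adjusted p = 0.313). None of 15 type 2 cytokine and pruritogen genes passed (median 0.12, camera adjusted p = 0.108), and the alarmin Il33 was at 48.8 ± 7.45 and 47.0 ± 5.59 (-0.05, SE 0.13, adjusted p = 0.859). None of 23 chemokine genes passed (median 0.17, camera adjusted p = 0.137). In the NF-kB list Ptgs2 was the 1 of 17 genes that rose, 2 when adjusted over the list alone (median 0.10, camera adjusted p = 0.105).

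Markers of spinal neurons did not pass as lists. The median log2 fold changes were 0.08 for 11 motor and cholinergic, 0.01 for 13 excitatory dorsal horn, 0.06 for 13 inhibitory and 0.34 for 7 primary sensory neuron genes, with camera adjusted p of 0.563, 0.705, 0.108 and 0.185. The first 3 of these medians turn negative after TPM scaling, at -0.015, -0.083 and -0.035, and the mean of the excitatory list is -0.009. Pdyn was the only member of the 4 lists that passed over all genes, and 2 inhibitory neuron genes passed adjusted over the list alone. None of 23 ionotropic receptor genes passed (median -0.06, camera adjusted p = 0.245). Of 18 TRP and sodium channel genes Trpm7, a magnesium-permeable channel, fell, over all genes and over the list alone (-0.49, SE 0.08, adjusted p = 0.0259; list median -0.08, camera adjusted p = 0.105). After removal of the length and GC trend the medians of the last 2 lists are positive, at 0.068 and 0.011.

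**Figure D2:**
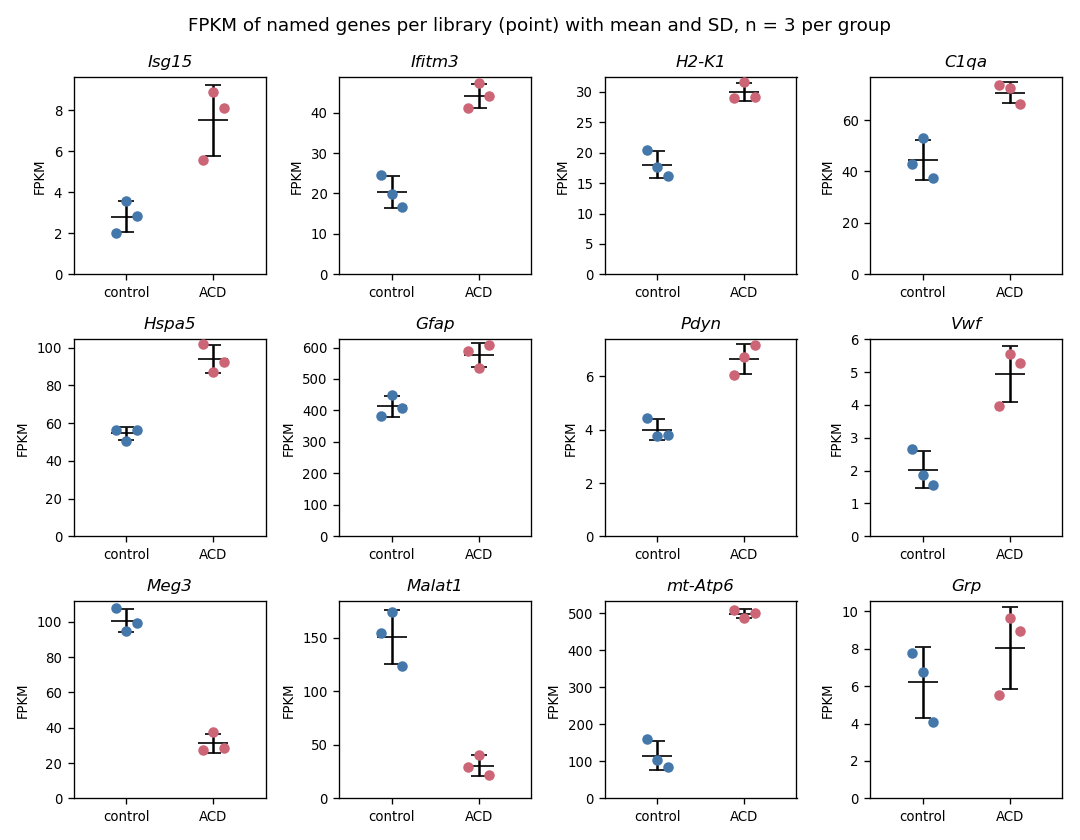
FPKM (vertical axes, from 0) of 12 genes in each control (blue) and ACD (red) library, with the group mean and SD (n = 3). In 11 of the 12 genes the groups do not overlap; Grp overlaps, at 6.20 ± 1.90 and 8.05 ± 2.19 FPKM.

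Many long non-coding RNA genes were lower in ACD. Of 1527 long non-coding genes with at least 10 mean reads 124 fell and 3 rose, with a median log2 fold change of -0.27, against 265 lower and 278 higher of 14480 protein-coding genes with a median of 0.03. Malat1, on chromosome 19 at 5795690 to 5802672, fell by 2.33 on the log2 scale (SE 0.23, adjusted p = 0.00873), and Meg3, on chromosome 12 at 109541001 to 109571726, by 1.70 (SE 0.12, adjusted p = 0.00417). C78859 fell from 2.41 ± 0.237 to 0.687 ± 0.130 FPKM (-1.68, SE 0.17, adjusted p = 0.00870) and Phf2os1, annotated as antisense, from 4.17 ± 0.426 to 1.31 ± 0.497 (-1.66, SE 0.24, adjusted p = 0.0196). With voom 254 of 1474 fell and 10 rose, and after removal of the length and GC trend 110 of 1527 fell and 10 rose. The class median stayed negative under each scaling tried, from -0.35 after TPM scaling to -0.18 after removal of the length and GC trend. Of 20 small RNA genes with at least 10 mean reads 4 fell and 1 rose (median -0.90), and after removal of that trend 1 fell and 3 rose (median -0.56). The small RNA genes among the largest falls rested on few reads: Mir5100 had 1, 3 and 4 reads in the controls, Snord49b 5, 3 and 1 and Mir491 7, 2 and 1, each with 0 in all ACD libraries. Rnu73b had 4, 7 and 4 against 0, 0 and 1, and Mir421 9, 18 and 7 against 2, 4 and 2. Mir1291, with 41.9% of its words shared, had 5, 3 and 5 against 2, 1 and 1. Reads in long non-coding genes came to 1.32% ± 0.0356 of the denominator in controls and 0.952% ± 0.0470 in ACD. Those in small RNA genes came to 0.0107% ± 0.000814 and 0.00530% ± 0.000265 (SD, n = 3). All recovered reads summed to a mean of 1.007 times the denominator in controls and 1.0566 times in ACD.

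Of 13 mitochondrially encoded mRNAs 3 rose and none fell, 5 rose when adjusted over the list alone, with a median of 0.02 that becomes -0.08 after TPM scaling and a mean of 0.65 (camera adjusted p = 0.0355; adjusted p = 0.520 with an estimated correlation). They were mt-Atp6, a subunit of ATP synthase, at 115 ± 39.5 and 499 ± 11.9 FPKM (2.16, SE 0.21, adjusted p = 0.00870), and the cytochrome oxidase subunits mt-Co3, at 68.8 ± 20.0 and 290 ± 69.8 (2.09, SE 0.24, adjusted p = 0.0108), and mt-Co2 (1.21, SE 0.21, adjusted p = 0.0283). These 3 genes share 99.5%, 99.9% and 99.5% of their words with nuclear gene models, so their values are uncertain. mt-Co1, with far higher FPKM at 15070 ± 1809 and 14670 ± 1682, did not pass (-0.04, adjusted p = 0.891). The 5 mRNAs with at least 90% shared words lay at 68.8 to 200 FPKM in controls. The other 8 lay at 2430 to 15070, apart from mt-Atp8 at 8.93. The gap in FPKM therefore need not be one of mRNA abundance, since the counting of shared reads is not given. The nuclear oxidative phosphorylation genes had 2 of 22 higher, Uqcrq (0.57, adjusted p = 0.0327) and Cox7a2 (0.43, adjusted p = 0.0384), and 11 when adjusted over the list alone (median 0.26, camera adjusted p = 2.45e-05; adjusted p = 0.507 with an estimated correlation). Protein-coding genes with a short total exon length were higher in general. The median log2 fold change ran from 0.17 in the eighth with the shortest total exon lengths to -0.09 in that with the longest. Each eighth held 1515 or 1516 genes, so not all tested protein-coding genes were included.

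Markers of blood, peripheral myelin, muscle and fat were unevenly spread over the libraries. The 4 haemoglobin genes summed to 98.1, 275 and 384 FPKM in controls 1 to 3 and to 475, 763 and 551 in ACD 1 to 3. None of 9 erythroid genes passed, over all genes or the list alone (median 0.90, camera adjusted p = 0.00851; adjusted p = 0.507 with an estimated correlation). None of 15 neutrophil genes passed over all genes and 2 did so adjusted over the list alone (median 1.23, camera adjusted p = 4.78e-04; adjusted p = 0.507 with an estimated correlation). Control 2 lay at or near the ACD level for some of them, with S100a9 at 55.87 FPKM against 11.89 and 12.04 in controls 1 and 3 and 44.07 to 54.25 in ACD. Without control 2 the median was 1.59 and S100a9, S100a8, Ngp, Camp, Lcn2 and Ltf passed over all genes, while without control 1 or 3 it was 0.84 or 0.88 and none passed. The 6 T and NK cell genes had no call over all genes and 2 over the list alone (median 0.69, camera adjusted p = 0.0355; adjusted p = 0.491 with an estimated correlation), and the 7 B and plasma cell genes had none (median 0.15, camera adjusted p = 0.552). None of 10 Schwann cell genes passed over all genes and 6 were higher adjusted over the list alone (median 0.70, camera adjusted p = 2.45e-05; adjusted p = 0.491 with an estimated correlation).

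None of 12 oligodendrocyte genes passed over all genes and 1, Mal, did so adjusted over the list alone (median 0.32, camera adjusted p = 0.00244; adjusted p = 0.507 with an estimated correlation), and none of 10 oligodendrocyte precursor genes passed over all genes and 3 over the list alone (median 0.19, camera adjusted p = 0.0438; adjusted p = 0.491 with an estimated correlation). Skeletal muscle genes had no call among 10 over all genes and 2 lower over the list alone (median -1.35, camera adjusted p = 0.0132; adjusted p = 0.528 with an estimated correlation). Control 2 had the highest value for 9 of the 10, all but Pvalb (122 FPKM, against up to 139 in ACD). Tnnt3 was at 5.61 FPKM there against 1.23 and 0.692 in the other controls and 0.0345 to 0.219 in ACD. Adipocyte genes had no call among 8 (median -2.38, camera adjusted p = 0.122). Each was highest in control 1, where Fabp4 was at 68.9 and Ucp1, the uncoupling protein of brown fat, at 51.8 FPKM, against at most 0.216 for Fabp4 and 0 for Ucp1 in controls 2 and 3. No gene passed among 10 pericyte (median -0.08, mean 0.006, camera adjusted p = 0.818) and 9 ependymal markers (median -0.05, camera adjusted p = 0.396), nor over all genes among 12 meningeal fibroblast markers, 2 of which were higher over the list alone (median 0.23, camera adjusted p = 0.122). None of the 4 sex-linked genes tested passed (median -0.28, camera adjusted p = 0.0687).

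**Figure D3:**
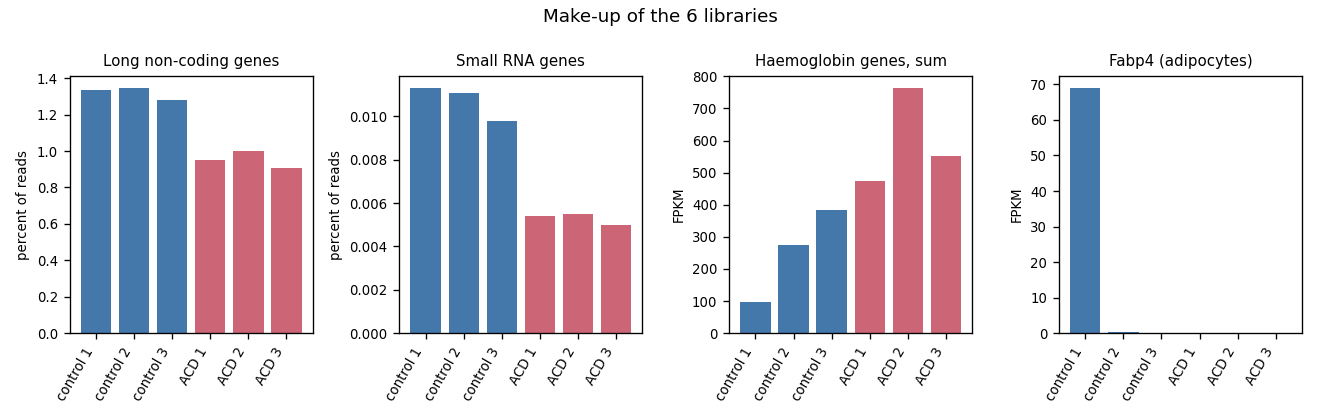
Reads in long non-coding and in small RNA genes as a percent of the library's denominator, summed FPKM of 4 haemoglobin genes and FPKM of Fabp4 (vertical axes, from 0). There is 1 bar for each of the 6 libraries, controls in blue and ACD in red. The long non-coding share is 1.28% to 1.35% in controls and 0.905% to 0.999% in ACD, and Fabp4 stands at 68.9 FPKM in control 1 alone.

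The counts rest on few animals: with 1 library left out, 274 genes passed without control 1, 615 without control 2, 736 without control 3, and 282, 299 and 192 without ACD 1, 2 and 3. Of the 41 lists 21 passed camera at the preset correlation, 19 higher and 2 lower, and none with an estimated correlation, where the adjusted p ran from 0.491 to 0.879.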

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

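The settings with a read minimum, the length and GC trend removed, median-of-ratios scaling, TPM scaling or protein-coding nuclear genes alone were chosen after seeing the data. Each of the 927 genes that passed kept its sign in every setting that tested it. The groups do not overlap in any of these genes. Leaving out a library or changing the pseudocount, filter, threshold or replicate block could therefore not turn a sign, and the kept signs are no support. Pseudocounts of 0.01 and 1, upper-quartile scaling, leaving out dominant transcripts and protein-coding nuclear genes alone left between 777 and 969 genes passing. Median-of-ratios scaling gave 928, all 927 among them, with the median log2 fold change of all genes at -0.0099 as before. It left the values nearly unchanged, so its result is no independent check. TPM scaling gave 912 (208 higher, 704 lower), 746 of them shared with the 927. Of the 53 named genes that passed, 12 passed in each setting that tested them. They were Hspa5, Hsp90b1, Cdkn1a, Ctla2a, Malat1, Meg3, C78859, Sprr1a, Mir5100, mt-Atp6, mt-Co3 and mt-Tl1. Mir5100 rests on few reads and the values of mt-Atp6 and mt-Co3 are uncertain, so passing in each setting does not make a value sound. The others passed in fewer: of 20 settings, Isg15 passed in 16, Gfap and C1qa in 13, Tmem119 in 12 and Apold1 in 11. Of the 8 named genes that did not pass, Lcn2 and Aif1 passed 0.05 in 1 setting each, without control 2. The planned count test, a quasi-likelihood F test in edgeR with its own scaling factors, was not run, since the files hold no counts. Scaling by the total of recovered reads was not run either. That total was 0.976 to 1.068 times the denominator of the FPKM, so the FPKM as deposited are not scaled by it.

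The count rose to 2474 (1203 higher, 1271 lower) with voom on recovered reads, to 2076 (945, 1131) at a threshold of 0.10 and to 1392 (888 higher) with the length and GC trend removed. With at least 10 recovered reads in at least 3 libraries 1285 genes passed (593 higher, 692 lower), and after TPM scaling 912 (208 higher, 704 lower). With at least 1 FPKM in at least 3 libraries 1033 passed, and more were higher (542) than lower (491). Without a filter the count fell to 556 (221 higher, 335 lower), with more genes tested. Lists past camera fell to 13 with a minimum of 1 FPKM, to 0 with an estimated correlation and to 1 by fry's directional p (25 by its p for changes in either direction). For the other changes the cause was not tested. The labels number the mice 1 to 3 in both groups, but deviations of same-numbered libraries correlated at -0.071, 0.077 and 0.05, so the numbers are not taken as pairs; a fit with the replicate block passed 181 genes (86 higher, 95 lower), with fewer residual degrees of freedom.

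With 1 library left out, and so fewer samples, 192 (without ACD 3) to 736 (without control 3) genes passed, with 274 without control 1, 615 without control 2, 282 without ACD 1 and 299 without ACD 2. Of these 65 to 378 were higher and 127 to 358 lower, and 16 to 21 lists passed.

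Some values changed sign, none of a gene that passed; of the lists only the mitochondrially encoded mRNAs had passed camera. Il33 was at 0.058 with voom, 0.042 with the length and GC trend removed and -0.176 to 0.048 with 1 library left out; Grpr at 0.009 with that trend removed and -0.223 to 0.178; and Npr1 at -0.452 to 0.013. The trend removal also turned the ionotropic receptor list (0.068) and the TRP and sodium channel list (0.011). TPM scaling turned the motor (-0.015), excitatory (-0.083) and inhibitory (-0.035) neuron lists and the mitochondrially encoded mRNAs (-0.078), and voom the excitatory list (-0.007). B and plasma cell genes were at -0.055 with no filter and -0.012 among protein-coding nuclear genes. With 1 library left out the list medians ran from -0.01 to 0.395 for B and plasma cell, -0.227 to 0.03 for endothelial, -0.124 to 0.219 for motor, -0.068 to 0.113 for excitatory and -0.035 to 0.183 for inhibitory neuron genes. They ran from -0.101 to 0.571 for meningeal, -0.063 to 0.096 for mitochondrially encoded, -0.259 to 0.014 for pericyte and -0.228 to 0.005 for ependymal genes. The cause of these changes of sign was not tested. Depth limits the low end: 136 of the 927 calls rest on a mean of under 10 reads.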

Other observations

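The tests on depth, gene models in introns, nuclear copies, whole mitochondrial output and haemoglobin were chosen only after the results were seen. Among gene groups not described above, and chosen after their values were seen, 15 of 82 ribosomal protein genes rose and 1 fell, with a median log2 fold change of 0.26 that lay between 0.16 (11 higher, 1 lower) after TPM scaling and 0.30 (31 and 1) with the length and GC trend removed; with voom 37 of 76 rose and 2 fell. Pseudogene models with at least 10 mean reads had 83 higher and 27 lower of 687, with a median of 0.07 that was -0.02 (69 and 40) after TPM scaling and 0.20 (133 and 21) with the trend removed, so no direction is given for them.

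The real grouping gave 927 passing genes, against at most 6 in the other 9 of the 10 splits of the 6 libraries into 3 and 3; for higher genes it gave 386 against at most 5, and for lower genes 541 against at most 5. Only 1 split, the real one, gave each count. For lists past camera the real grouping gave 21, against 17 in the highest of the others, so many lists also pass in groupings that mix the mice. With 10 splits a share under 0.05 cannot be reached.

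Long non-coding genes were lower in ACD, with 124 lower and 3 higher of 1527 (254 and 10 of 1474 with voom). A trend on exon length and GC content may account for part of it but not the whole: with the trend removed, the median of the 1527 genes moved from -0.27 to -0.184. The 124 lower genes had a median of -1.239 (-1.34 before), and 106 still passed. They were picked for their falls in these data, so their median does not decide it. The median of 20 small RNA genes moved from -0.90 to -0.56. Lower depth is excluded: the mean denominator of the ACD libraries was 1.058 times that of the controls. The recovered reads summed to a mean of 1.0566 times the denominator in ACD and 1.007 times in controls. A lower share of unspliced RNA in the ACD libraries may be part of the cause: the 195 long non-coding models inside introns of protein-coding genes had a median of -0.625 (42 lower, 0 higher) and the 663 outside such genes -0.225 (47 lower, 2 higher), with the 669 that overlap such genes otherwise left out of the test (median -0.247; 35 lower, 1 higher), a difference of -0.401 (bootstrap 95% interval -0.577 to -0.241; two-sided permutation p = 1e-04, the smallest that the permutations run can give), and 20 pseudogene models in introns, with under 10% shared words, lay below 125 outside by 0.647 (interval of the difference -1.219 to -0.022; p = 1e-04). These intervals and p-values measure the spread over gene models, all measured in the same 6 libraries, and not the spread over mice. They therefore do not show that the share differs between ACD and control mice in general. The interval of the pseudogene models also nearly reaches 0. A lower share of unspliced RNA leaves the lower values of the other models open. An effect of the challenge, which was not tested, stays open for all of them.

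The mitochondrial mRNAs mt-Atp6, mt-Co3 and mt-Co2 were higher in ACD while mt-Co1, mt-Cytb and mt-Nd1 were not. Higher output of the whole mitochondrial genome is excluded, since the 8 mitochondrial mRNAs with under 90% of their words in other genes had a median of -0.078 (quartiles -0.108 and 0.016), against 2.09 for the 3 genes. Reads that also fit nuclear copies, and so depend on how shared reads were assigned, stay open as a candidate explanation: each of the 3 genes has at least 90% shared words, but so have only 2 other mRNAs, mt-Nd4l at 1.70 (adjusted p = 0.0956) and mt-Nd3 at 0.02 with 97.8%, which exceeded the 8 below 90% by 0.935 in median (two-sided exact permutation test, p = 0.133 over 45 arrangements), too few to decide. The 7 tested nuclear gene models with at least 50% of their words in a mitochondrial gene, all between 24611535 and 24616197 on chromosome 1, rose as well (median 1.40; 6 of the 7 passed after TPM scaling and 4 with voom). The flat mt-Nd3 stands against a simple account. mt-Atp8, with 0% shared words, was at 1.76 (adjusted p = 0.0664), and the tRNA gene mt-Tl1, which is 1 word long and has 0%, was at 1.74 (adjusted p = 0.00923). Words were compared between annotated gene models only, so 0% does not show that a nuclear copy is missing, and mt-Atp8 and mt-Tl1 do not decide it. Why the assigned reads differ by group stays open, an effect of the challenge included.

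Interferon-stimulated and antigen presentation genes were higher in ACD, with a median of 0.605 over 48 genes. A trend on length and GC content is excluded as the cause (median 0.67 with it removed, 44 of 48 above 0), and so is sharing of reads between paralogs (median 0.592 over the 40 genes with under 10% shared words). More blood in the ACD cords may contribute: the lowest haemoglobin sum of an ACD library exceeded the highest of a control by 91.3 FPKM. The mean of the 48 genes was 1.14, 1.02 and 0.78 (log2 scale) in the controls with 98.1, 275 and 384 FPKM of haemoglobin, and 1.48, 1.53 and 1.66 in the ACD libraries with 475, 551 and 763 FPKM, so the order differs between the groups, and 3 libraries in each do not decide it. An effect of the challenge on the cord was not tested apart from blood and stays open.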
